A study of Mus musculus with 12 samples.

How the data were processed

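Total RNA including small RNA was isolated from mouse brain tissue with a column kit and ligated to miRNA tags before the nCounter assay, per the labels' protocols. The panel was the nCounter mouse miRNA panel of 599 barcodes, per the series' design text. The deposited table holds 1 normalized signal value per probe and sample, per the file headers and the values. The software, background correction and normalization are not given in the sources used here.

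The values themselves were tested for what they are. In each of the 12 samples every value was a whole multiple of 1 step (100% of values, within 0.05 of a count), so the deposited signal is a whole barcode count multiplied by 1 factor per sample. The factors ranged from 0.982 to 2.28 units per count. The geometric mean of the 100 most abundant probes was equal in all samples (1133.38), so the factors scale each library to those probes. The lowest deposited signal was 1 count times the factor in every sample except WT cortex replicate 2, where it was 1.00 while 1 count is 0.98 signal units. Dividing by the step gave the counts and the library depth. A value near the viral mean of 53.1 rests on few counts and on background.

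Samples were grouped by genotype and region from the labels, with 3 samples per group and 12 months of age throughout. Probes were named as in the deposited table, 9 of them covering more than 1 miRNA. The 33 viral probes (23 of mouse cytomegalovirus, 10 of mouse gammaherpesvirus) were kept out of the tests and used as a measure of background, since the table has no negative-control probes. Mouse probes with a mean over all samples of at least 20 entered the tests (467 of 566), and 99 were left out.

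The main test was limma (version 3.58.1, R 4.3.3) on log2(value + 1), with lmFit, contrasts.fit and eBayes in 1 fit of the 4 groups and all 12 samples, so that the groups share 1 estimate of the spread. Adding 1 shrinks the fold changes of low miRNAs slightly. The comparisons were APP/PSEN1 against WT in cortex, in hippocampus and as their mean, the difference between these genotype effects, and hippocampus against cortex in each genotype. Calls are at a Benjamini-Hochberg adjusted p of 0.05 over the tested miRNAs. The design assumed normalized values or raw counts; the table held normalized values from which counts could be recovered, so limma stayed the main test, and edgeR's quasi-likelihood test (4.0.16, TMM) and DESeq2 (1.42.0) on the recovered counts were added as alternatives. An adjusted p that DESeq2 left empty was not counted (37 in the WT region comparison, 244 in the APP/PSEN1 one). Tests of a single value between groups were exact two-sided permutation tests.

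The median 95% interval of a fold change between 2 groups reached 0.68 log2 units (1.60-fold) to either side, and 0.52 (1.43-fold) for miRNAs above the viral threshold. The statistics were tested on simulated data over 467 miRNAs in 20 draws. Each miRNA was drawn from its mean over all 12 samples and the real depths, with changes placed in APP/PSEN1 cortex. With 20 miRNAs changed, 3.57% of 1.5-fold, 32.9% of 2-fold and 96.7% of 4-fold changes were found and 4.52% of calls were unchanged miRNAs. With 200 changed, 30% of 1.5-fold, 79.5% of 2-fold and 99.8% of 4-fold changes were found, with 2.44% false. A list raised 2-fold was found in 20 of 20 draws, and 2 of 310 unchanged lists were called. The miRNAs were drawn independently, so these shares leave out correlation between miRNAs and background shifts that they share. With the real values, other splits of the cortex libraries called up to 7 lists.

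The text names, in each comparison, the 12 miRNAs with the largest positive and the 12 with the largest negative log2 fold change among those that passed. Where fewer than 10 passed, it names the 10 with the lowest p as values that did not pass. It also names both miR-7 probes, and for each list described up to 4 members with the lowest p. Fixed lists (21) covered the miR-7, let-7 and miR-98, miR-29, miR-30, miR-34, miR-181 and miR-17-92 families, the Dlk1-Dio3 and Sfmbt2 clusters, and neuron-enriched, activity-regulated, oligodendrocyte-enriched, astrocyte-enriched, microglia and myeloid, inflammation-responsive, endothelial and mural, erythrocyte, choroid plexus and ependyma, other brain regions and epithelium, muscle and liver, and App or Bace1 targeting miRNAs. Each of 19 lists with at least 3 tested members was tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, with the tested miRNAs as background. The miR-7 and miR-181 families had 2 members each and were not tested as lists; miR-181a and miR-181c had log2 fold changes of -0.34 and -0.36 for APP/PSEN1 against WT in cortex and did not pass.

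The alternatives fixed before the data were examined were no filter, a mean of at least 50, pseudocounts of 0.5 and 10, scaling to the 100 most abundant miRNAs, quantile normalization, median centring, limma with trend and robust settings, only the 2 groups compared, replicate number as a block, genotype and replicate number as a block, and leaving out each library. Chosen after seeing the data were both count tests, a filter at the viral threshold, the viral mean subtracted or as a covariate, leaving out 2 libraries (APP/PSEN1 hippocampus replicate 1, with the lowest depth and background, and WT cortex replicate 1, with the highest background), and the region comparison averaged over genotypes. No genome was used, and no coordinates are given because the table names no genome build.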

Results

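MicroRNAs (miRNAs), short RNAs that lower the output of messenger RNAs carrying matching sites, were counted in total RNA from the brains of 12-month-old mice. The assay was nCounter, which ligates each miRNA to a tag, binds it to a fluorescent barcode and counts barcodes without amplification. The 12 samples fell into 4 groups of 3: cortex and hippocampus of wild-type (WT) mice, and cortex and hippocampus of APP/PSEN1 mice, a transgenic model of Alzheimer's disease that carries altered amyloid precursor protein and presenilin genes. All 12 samples carry the same strain label, and the labels do not say whether the WT mice were littermates of the APP/PSEN1 mice, so a genotype difference here is a difference between the labelled groups. The labels number the samples of a group without saying that each came from a separate animal, so p-values measure the spread between these samples. Of the 599 probes, 566 were for mouse miRNAs and 33 for miRNAs of mouse herpesviruses. The viral probes served as a measure of background.

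Library depth, the sum of barcode counts over the probes, was 298387, 423176 and 385823 in WT cortex and 350344, 375216 and 308965 in APP/PSEN1 cortex. It was 326827, 326648 and 215212 in WT hippocampus and 179161, 317403 and 210262 in APP/PSEN1 hippocampus. The most abundant probes were let-7g or miR-124 in cortex and miR-9 or miR-720 in hippocampus. Viral probes averaged 66.8 ± 22.7 (SD, n = 3) in WT cortex, 55.9 ± 15.0 in APP/PSEN1 cortex, 48.5 ± 9.52 in WT hippocampus and 41.0 ± 10.9 in APP/PSEN1 hippocampus, in units of the deposited normalized signal. Exact two-sided permutation tests of depth and of the viral mean between groups gave p from 0.2 to 0.6, where 0.1 is the smallest p that 3 against 3 samples allow. Of 467 mouse miRNAs tested, 151 had a mean signal above 109.42, the mean of the viral probes plus 2 SD, and 316 lay below it.

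**Figure D1:**
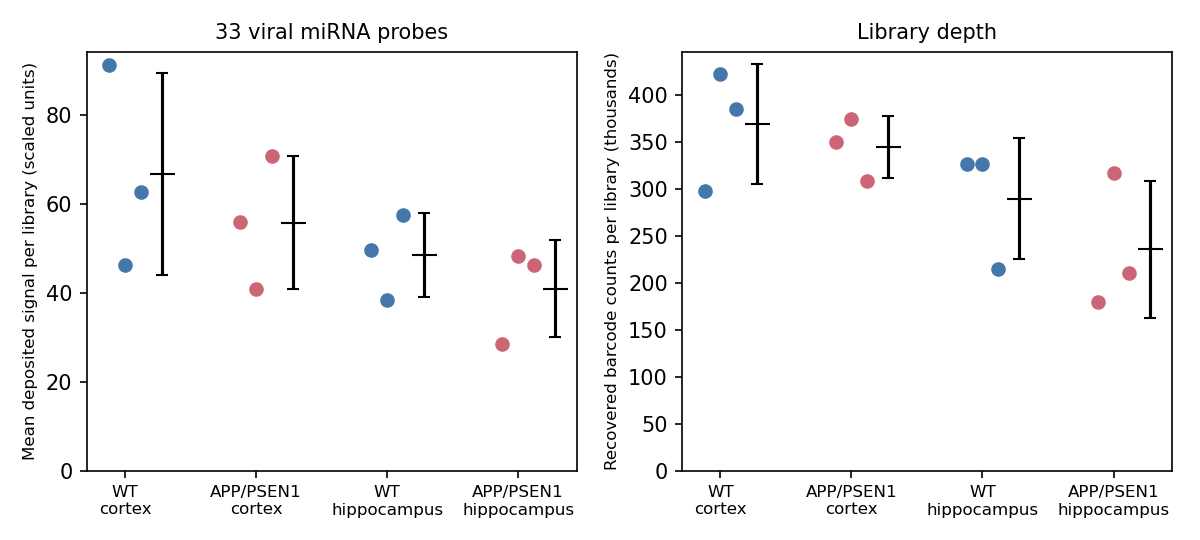
Mean deposited signal of the 33 viral miRNA probes (left, scaled units) and recovered barcode counts per library (right) in the 4 groups. Points are libraries, bars are the group mean ± SD (n = 3); WT cortex replicate 1 has the highest viral mean (91.3) and APP/PSEN1 hippocampus replicate 1 the lowest viral mean (28.5) and depth (179161).

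The fold changes of all tested miRNAs were not centred on 0. Their median log2 fold change was -0.18 for APP/PSEN1 against WT in cortex, -0.12 in hippocampus, and -0.31 and -0.21 for hippocampus against cortex in WT and APP/PSEN1. Centring each library on its median moved these medians to 0.03, 0.09, 0.03 and 0.13, and quantile normalization moved them to -0.00097, -0.0067, -0.026 and -0.028. The 316 tested miRNAs below the viral threshold had median region differences of -0.37 in WT and -0.28 in APP/PSEN1. The 151 stronger ones had -0.10 and -0.00072. Median centring therefore shifts the stronger miRNAs by a region difference seen mainly in the low-signal ones. Every fold change given here is relative to the 100 most abundant probes, to which the deposited values are scaled, unless another scaling is named.

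The series title names miR-7a, an miRNA known to lower Klf4, a transcription factor with a part in inflammatory signalling, so the miR-7 family was examined for a genotype difference before other miRNAs. Its panel members were miR-7a, made from the genes Mir7-1 and Mir7-2, and miR-7b, made from Mir7b. In cortex miR-7a measured 326 ± 3.55 (SD, n = 3) in WT and 680 ± 159 in APP/PSEN1, and limma's fold change, from the means of log2 values, was 2.05 with a 95% confidence interval of 1.16 to 3.62. All 3 APP/PSEN1 cortex libraries (510, 708 and 824) lay above all 3 WT libraries (329, 325 and 322). In hippocampus it measured 227 ± 19.1 in WT and 434 ± 227 in APP/PSEN1, and limma's fold change was 1.68 with an interval of 0.95 to 2.97. There, 2 APP/PSEN1 libraries measured 584 and 546 and the other measured 173, below the lowest WT value of 207.

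None of these differences passed the test over all 467 miRNAs. The limma adjusted p of miR-7a was 0.813 in cortex (log2 fold change 1.03, SE 0.38), 0.966 in hippocampus (0.75, SE 0.38) and 0.815 for the mean of both regions (0.89, SE 0.27; 1.85-fold, interval 1.24 to 2.77). miR-7a had the lowest unadjusted p of all tested miRNAs for the mean of both regions, and ranked 6 in cortex and 11 in hippocampus. Adjusted over the list alone, the limma p of miR-7a was 0.0353 in cortex, 0.142 in hippocampus and 0.0112 for the mean of both regions. The family was taken from the series title, and the labels do not say whether that title rests on these samples, so the list-alone and exact p of miR-7a are not tests on independent data. Exact two-sided permutation tests of miR-7a gave p = 0.1 in cortex, the smallest possible, p = 0.4 in hippocampus, and p = 0.02 for both regions with labels permuted within region (400 arrangements). That last test, like the limma, edgeR and DESeq2 tests of the mean, treats cortex and hippocampus samples as independent. The labels do not say whether those samples came from the same mice, and if so these p may be too small. miR-7b measured 197 ± 14.2 and 268 ± 25.0 in WT and APP/PSEN1 cortex, and 179 ± 65.8 and 202 ± 84.6 in hippocampus (n = 3 each). Its log2 fold changes were 0.44 (SE 0.34) in cortex and 0.13 (SE 0.34) in hippocampus, with adjusted p of 0.934 and 0.966 by limma.

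The call of miR-7a depended on the test and on 1 library. On recovered barcode counts, miR-7a passed for the mean of both regions in edgeR's quasi-likelihood test (log2 fold change 1.15, adjusted p = 0.00847) and in DESeq2 (1.15, adjusted p = 0.000186), and in DESeq2 also in cortex (1.29, adjusted p = 0.0233). APP/PSEN1 hippocampus replicate 1, the library with the least depth, is also the one with miR-7a at 173. Leaving it out had to raise the fold change, so that run gives no separate support for a call. Without APP/PSEN1 hippocampus replicate 1, limma gave 1.17 and an adjusted p of 0.0051 for the mean of both regions, and 1.32 and 0.0758 in hippocampus. Without replicate 2 or 3 of that group, the hippocampal log2 fold change was 0.44 or 0.49. Over every alternative run, the adjusted p ranged from 0.0233 to 0.994 in cortex, from 0.0758 to 0.998 in hippocampus and from 0.000186 to 0.999 for the mean, and the log2 fold change stayed above 0 in each.

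**Figure D2:**
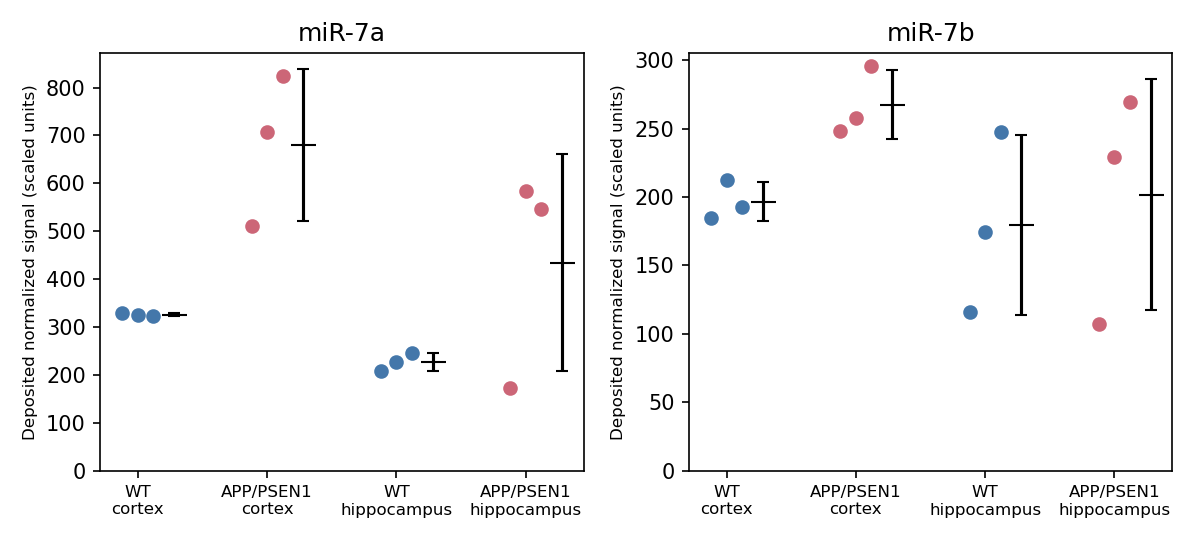
Deposited normalized signal of miR-7a (left) and miR-7b (right) in the 4 groups; points are libraries and bars the group mean ± SD (n = 3). The 3 APP/PSEN1 cortex libraries lie above the WT cortex libraries for both miRNAs, and 1 APP/PSEN1 hippocampus library has 173 for miR-7a, below the WT hippocampus libraries.

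In cortex, the comparison of APP/PSEN1 with WT asks which miRNAs differ with the transgenes. Of the 10 miRNAs with the lowest p, miR-7a was higher on average in APP/PSEN1 and the other 9 lower, and none passed the test. The 9 were miR-696 (64.8 ± 19.8 in WT and 24.8 ± 3.82 in APP/PSEN1, n = 3 each; log2 fold change -1.32, SE 0.30, limma adjusted p = 0.367), miR-1896 (-0.93), miR-471 (-0.86), miR-691 (-0.80), miR-653 (-0.77), miR-34a (-0.69), miR-151-3p (-0.69), miR-687 (-0.65) and miR-193 (-0.63). Except for miR-34a, which is switched on by the tumour suppressor p53 and measured 113 ± 22.8 and 69.0 ± 7.47, they had group means below 65 in both cortex groups. All 9 had a mean over all samples below the viral threshold, and the viral probes themselves had a median log2 difference of -0.27 in the same comparison. No miRNA passed limma at an adjusted p of 0.05, and 28 had an unadjusted p under 0.05, where 23.35 would do so by chance. edgeR called 0 (21 unadjusted) and DESeq2 called 1, miR-7a.

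The let-7 and miR-98 family, which is abundant in mature neurons and glia, was the only list that passed limma's camera test (adjusted p = 0.01003, higher relative to the other miRNAs), and it did not pass with an estimated correlation (adjusted p = 0.601) or among the 151 miRNAs above the viral threshold (adjusted p = 0.260), where all 9 members lie. Its median log2 fold change was 0.11, 6 of its 9 members had positive values, and let-7a (0.51, SE 0.23; 6180 ± 712 and 8775 ± 474) and let-7f (0.42, SE 0.22) had the lowest p. No member passed, and fry gave the list an adjusted p of 0.540. Without the 2 libraries at the extremes of background and depth, camera gave the family an adjusted p of 0.0583.

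The microglia and myeloid list had an adjusted p of 0.0765 in cortex. It had 5 of 9 members above 0, a median of 0.03, and miR-146a, an miRNA induced by the inflammatory factor NF-kB, at 0.50 (SE 0.23; 247 ± 48.5 and 345 ± 19.4). Among the 5 oligodendrocyte-enriched miRNAs all had values below 0, with miR-219 at -0.54 and miR-338-3p at -0.46, both known to act in myelinating cells; camera gave the list 0.562 and fry 0.299. Neuron-enriched miRNAs (4 of 15 above 0, adjusted p = 0.545) went both ways, with miR-153 at 0.55 and miR-129-5p at -0.49. The Dlk1-Dio3 cluster had an adjusted p of 0.0765, the miR-29 family 0.0886, miRNAs that target App or Bace1 0.141, and the miR-17-92 and miR-34 families 0.323. Adjusted p lay between 0.562 and 0.995 for the other 11 lists: activity-regulated, oligodendrocyte, astrocyte, inflammation-responsive, endothelial and mural, erythrocyte, choroid plexus and ependyma, other brain regions and epithelium, muscle and liver, miR-30 and Sfmbt2 cluster. Adjusted over the list alone, miR-34a was lower in the miR-34 family and no member of another tested list passed.

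In hippocampus the same comparison gave no passing miRNA, and the 10 lowest p went to miRNAs in both directions. Of those above the viral threshold, miR-128, a neuron-enriched miRNA, measured 1729 ± 135 (SD, n = 3) in WT and 1161 ± 223 in APP/PSEN1 (log2 fold change -0.59, SE 0.24). miR-148a measured 494 ± 63.9 and 787 ± 267 (0.61, SE 0.27), and miR-301a 363 ± 44.0 and 500 ± 27.2 (0.46, SE 0.20). The others, all below the threshold, were miR-700 (-1.08), miR-323-5p (-0.78), miR-2133 (-0.69), miR-223 (-0.58), miR-465c-5p (0.88), miR-1907 (0.72) and miR-210 (0.57), an miRNA induced by low oxygen. The lowest limma adjusted p was 0.966, with 8 unadjusted p under 0.05. edgeR called 0 (11 unadjusted) and DESeq2 0. The viral probes had a median log2 difference of -0.26.

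No list passed camera in hippocampus. The miR-17-92 cluster and its paralogs had the lowest adjusted p (0.329; median 0.10, 5 of 9 members above 0), and the other 18 lists had 0.940. Neuron-enriched miRNAs had 11 of 15 members below 0, a median of -0.19, and miR-153 at -0.51 and miR-129-5p at -0.36. The microglia and myeloid list had 5 of 9 members above 0, with miR-342-3p at 0.41 and miR-223 at -0.58. In the miR-34 family all 4 members had values below 0.

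Averaged over both regions, no miRNA passed limma (15 unadjusted); edgeR called 1 (13 unadjusted) and DESeq2 1, which was miR-7a in both. After miR-7a, the lowest p belonged to miR-691 (log2 fold change -0.57), miR-129-5p (-0.43), miR-148a (0.50), miR-696 (-0.55), miR-216a (-0.55), miR-700 (-0.59), miR-1306 (-0.51), miR-34a (-0.39) and miR-323-5p (-0.50). Of these, only miR-129-5p and miR-148a had a mean over all samples above the viral threshold. Here 2 lists passed camera, each by a small shift relative to the other miRNAs: the let-7 and miR-98 family (adjusted p = 0.00573, median 0.04, 7 of 9 above 0) and the microglia and myeloid list (adjusted p = 0.0331, median 0.05, 6 of 9 above 0). With an estimated correlation both had an adjusted p of 0.520, among miRNAs above the viral threshold both had 0.247, and fry gave 0.606 and 0.650. Without the 2 libraries at the extremes of background and depth, camera gave 0.0534 and 0.543. The remaining 17 lists had adjusted p from 0.0838 (Dlk1-Dio3 cluster) to 0.895 (activity-regulated).

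The difference between the genotype effects of the 2 regions was tested directly, and no miRNA passed limma (lowest adjusted p 0.766, 17 unadjusted), edgeR (15 unadjusted) or DESeq2. The lowest p belonged to miRNAs lower on average in APP/PSEN1 cortex and level or higher in hippocampus: miR-465c-5p (difference 1.67, SE 0.44), miR-696 (1.54), miR-471 (1.16), miR-208a (1.11), miR-504 (0.95), miR-1969 (0.94), miR-409-5p (0.86), miR-151-3p (0.85) and miR-301a (0.79). All of these except miR-301a had a mean over all samples below the viral threshold. miR-153 went the other way at -1.06 (SE 0.41), with 193 ± 39.5 and 285 ± 69.6 in WT and APP/PSEN1 cortex and 515 ± 71.9 and 374 ± 142 in hippocampus. The difference was -0.28 (SE 0.54) for miR-7a and -0.31 (SE 0.48) for miR-7b, and both turned positive without APP/PSEN1 hippocampus replicate 1. The median 95% interval of a difference between regions reached 0.96 log2 units (1.94-fold) to either side before adjustment over all miRNAs, so larger differences than that could also be missed. Of the lists, miR-17-92 and paralogs had the lowest adjusted p (0.166, all 9 members above 0), and the others had 0.553 to 0.996. Genotype effects in the 2 regions had a Pearson correlation of -0.06 across the 467 miRNAs, which are not independent replicates, and 0.04 across the 151 above the viral threshold.

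The same samples separated the 2 brain regions as labelled, though calls made with the labels do not test the labels. In WT, 51 miRNAs differed between hippocampus and cortex in limma, 21 higher and 30 lower in hippocampus. miR-9, a regulator of neural progenitors and among the most abundant brain miRNAs, rose from 11869 ± 2852 (SD, n = 3) in cortex to 27572 ± 528 in hippocampus (log2 fold change 1.24, SE 0.24, adjusted p = 0.00836). miR-132, which is transcribed in response to neuronal activity, fell from 30579 ± 5837 to 11877 ± 513 (-1.35, SE 0.22, adjusted p = 0.00353). miR-335-5p, hosted by the imprinted gene Mest, fell from 553 ± 137 to 160 ± 64.3 (-1.82, SE 0.33, adjusted p = 0.00565). miR-23a, which acts in oligodendrocyte differentiation, fell from 1636 ± 172 to 577 ± 77.5 (-1.51, SE 0.21, adjusted p = 0.00139).

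Among the largest increases were probes for small RNAs that have since been reclassified as tRNA fragments. miR-1937a+miR-1937b, 1 probe for both, rose from 182 ± 79.5 to 1300 ± 544 (2.81, SE 0.36, adjusted p = 0.00114), miR-1937c rose by 2.02, and miR-720 rose from 9759 ± 691 to 37557 ± 17128 (1.84, SE 0.29, adjusted p = 0.00349). The other named increases were miR-2141 (1.98), miR-2134 (1.68), the neuron-enriched miR-153 (1.42), miR-2133 (1.33), miR-669f (1.15), miR-222 (1.12; 77.2 ± 5.04 to 169 ± 7.44), miR-2132 (1.11) and miR-2140 (1.06). In WT hippocampus replicates 1, 2 and 3, miR-720 measured 21553, 35494 and 55623. In the same order rose miR-2141 (399, 685 and 1353), miR-2134 (62, 164 and 267) and miR-2133 (33.6, 40.4 and 76.2). So did miR-2140 (269, 281 and 472) and miR-2132 (19.2, 37.9 and 44), while miR-153, miR-222 and miR-669f did not. Whether these probes share a cause with miR-720 was not tested. The other named decreases were miR-1192 (-1.64), miR-696 (-1.57), miR-592 (-1.52), the muscle miRNA miR-1 (-1.44), miR-135a (-1.41), miR-2183 (-1.39), miR-211 (-1.31), miR-139-3p (-1.31) and miR-375 (-1.28). Of the 30 lower miRNAs, 19 had a mean signal below the viral threshold, against 5 of the 21 higher ones. The viral probes had a median log2 difference of -0.39 between the same groups, low-signal mouse miRNAs -0.37 and the 151 stronger ones -0.10.

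Activity-regulated miRNAs had 2 of 5 members that fell, miR-132 and miR-212 (-0.97, SE 0.23), which share a transcript, and 3 that did not pass; the median was -0.72. The oligodendrocyte-enriched list had 1 of 5 that fell, miR-23a, with miR-219 at -0.86 (adjusted p = 0.0626) and all 5 below 0. fry found both lists lower on balance (adjusted p = 0.00593 and 0.000884), while camera, which compares a list with the other miRNAs, did not (0.414 and 0.277). With each library centred on its median, fry's adjusted p was 0.702 for both and their medians stayed below 0. The let-7 and miR-98 family had 1 member that rose, let-7e (1.03, SE 0.23), and 1 that fell, let-7g (-0.93, SE 0.24; 45687 ± 9108 to 23625 ± 954), with camera's adjusted p at 0.0584. Adjusted over the list alone, 3 let-7 members rose and 1 fell, 2 activity-regulated miRNAs fell and 2 oligodendrocyte-enriched miRNAs fell.

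Neuron-enriched miRNAs had 3 members that rose, miR-153, miR-218 (1.03, SE 0.21; 6038 ± 152 to 12453 ± 1845) and miR-128 (0.89, SE 0.24), 1 that fell, miR-132, and 11 that did not pass (camera 0.277). In the inflammation-responsive list 3 rose, among them miR-9 and miR-222, and 2 fell, miR-132 and miR-125b-3p (-1.04, SE 0.22), of 11 (0.6001); 2 of these 5 are also neuron-enriched or astrocyte-enriched. Of 9 astrocyte-enriched miRNAs, miR-99a rose (0.94, SE 0.25) and miR-125b-3p fell (0.483). Of 17 miRNAs that target App or Bace1, miR-9, miR-153 and miR-101a (0.85, SE 0.23) rose (0.507). Of 52 in the Dlk1-Dio3 cluster, a run of imprinted miRNAs, miR-495 (0.95), miR-487b (0.78) and miR-376b (0.75) rose and miR-329 fell by 1.13 on the log2 scale (0.426). miR-1 and miR-208a (adjusted p = 0.0373) fell in the muscle and liver list (0.457), miR-211 fell among choroid plexus and ependyma miRNAs (0.865), miR-375 among those of other brain regions and epithelium (0.865), and miR-19a (-0.85) among miR-17-92 and paralogs (0.865). miR-669f rose in the Sfmbt2 cluster (0.865).

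No member passed among microglia and myeloid miRNAs (camera 0.457; miR-142-5p at 1.11, SE 0.37, adjusted p = 0.0735), endothelial and mural (0.717), erythrocyte (0.6001), miR-29 (0.865), miR-34 (0.865) or miR-30 (0.515) miRNAs. The sign of camera's test differed from that of the median for microglia and myeloid, inflammation-responsive, endothelial and mural, choroid plexus, App or Bace1, miR-17-92 and Dlk1-Dio3 lists, whose medians lay below 0 while camera ranked them higher than the other miRNAs. The median also differed in sign from the mean for microglia and myeloid miRNAs (-0.13 and 0.07).

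The count of 51 in WT stood beside 117 with an unadjusted p under 0.05, 59 in edgeR and 54 in DESeq2. The split changed with the scaling: 21 of 51 were higher as deposited, 32 of 51 after quantile normalization and 25 of 28 after median centring, and without WT hippocampus replicate 2 the count was 25.

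In APP/PSEN1 mice, 19 miRNAs differed between the regions, 9 higher and 10 lower in hippocampus. miR-9 rose from 11826 ± 900 to 24638 ± 5641 (1.04, SE 0.24, limma adjusted p = 0.0256), miR-99a from 1468 ± 78.7 to 3310 ± 654 (1.15, SE 0.25), and miR-204, which is abundant in choroid plexus, from 866 ± 124 to 1985 ± 358 (1.19, SE 0.23). miR-1937a+miR-1937b (1.87), miR-720 (1.42), miR-92b (1.24), miR-222 (1.02), miR-433 (1.01) and let-7e (0.88) also rose. miR-1 (-1.55), miR-139-3p (-1.47), miR-335-5p (-1.31), miR-23a (-1.19, adjusted p = 0.0158; 1569 ± 144 to 690 ± 71.2), miR-135b (-1.07), miR-212 (-1.05), miR-211 (-1.04), miR-190 (-1.01), miR-132 (-0.98) and miR-328 (-0.96) fell. Of these 10, 5 lay below the viral threshold; the viral probes had a median log2 difference of -0.34.

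No list passed camera in APP/PSEN1 mice (adjusted p 0.391 to 0.965). miR-132 and miR-212 fell among 5 activity-regulated miRNAs (median -0.78) and miR-23a among 5 oligodendrocyte-enriched ones, all 5 of which had values below 0. fry found both lists lower on balance (adjusted p = 0.0328 and 0.00396). The adjusted p was 0.828 and 0.635 after median centring, and 0.0620 and 0.0476 without the 2 libraries at the extremes. miR-433 rose and miR-132 fell of 15 neuron-enriched miRNAs, with miR-218 at 0.74 (adjusted p = 0.0746). Of the other lists, miR-204 rose and miR-211 fell among choroid plexus and ependyma miRNAs, miR-99a rose among astrocyte-enriched miRNAs, and no microglia and myeloid miRNA passed (miR-142-5p at 1.16, adjusted p = 0.0937).

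The count of 19 stood beside 101 with an unadjusted p under 0.05, 27 in edgeR and 45 in DESeq2, and 9 of 19 were higher as deposited, 12 of 23 after quantile normalization and 13 of 13 after median centring. It was 0 without APP/PSEN1 cortex replicate 1, cortex replicate 2, hippocampus replicate 1 or hippocampus replicate 3, and 3 without cortex replicate 3.

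The region differences of the 2 genotypes overlapped. Of 21 and 9 higher miRNAs, 6 were shared, where independent lists would share 0.405, and of 30 and 10 lower miRNAs 9 were shared, where 0.642 would be. The region fold changes had a Pearson correlation of 0.74 across the 467 miRNAs and 0.88 across the 151 above the viral threshold, and 49 of the 51 WT calls had the same sign in APP/PSEN1. The 2 comparisons share no library, but both use 1 estimate of the spread from all 12 samples. The viral probes also fell in both (median log2 difference -0.39 in WT and -0.34 in APP/PSEN1). The overlap expected without a shared region effect may therefore exceed 0.405 and 0.642. Whether the larger number of calls in WT reflects a difference between genotypes stays open, since no miRNA passed the test of that difference and its intervals are wide.

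**Figure D3:**
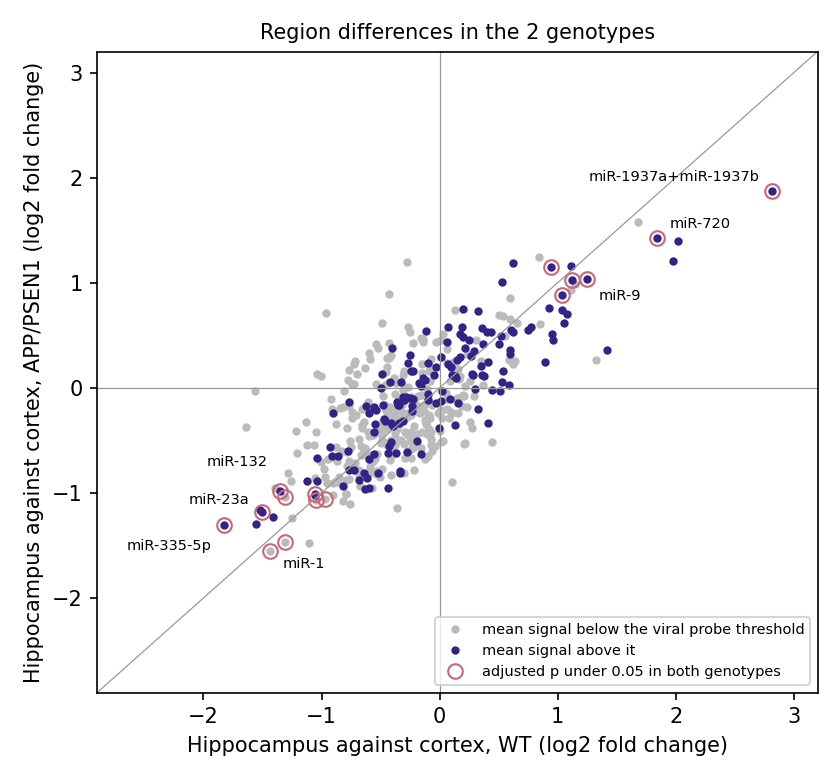
Log2 fold change of hippocampus against cortex in WT (horizontal) and APP/PSEN1 (vertical) for the 467 tested miRNAs, with dark points above the viral probe threshold, grey points below it and circles for an adjusted p under 0.05 in both genotypes. The 15 circled miRNAs lie near the diagonal, with miR-1937a+miR-1937b, miR-720 and miR-9 higher and miR-335-5p, miR-1, miR-23a and miR-132 lower in hippocampus.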

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

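The count tests, the viral filter, subtraction and covariate, and leaving out 2 libraries were chosen only after the results were seen. Of 85 named values that passed, none changed sign in any alternative run. The number still called was 85 with a pseudocount of 0.5 or scaling to the top 100, 84 with a pseudocount of 10, 83 with trend and robust settings, 82 with the viral covariate, 80 without a filter or with the replicate block, 73 after quantile normalization, 72 in edgeR, 67 in DESeq2 or without the 2 libraries, 60 to 77 without 1 library, 53 with the genotype and replicate block and 48 after median centring. The run scaled to the top 100 could not differ, since the deposited values are already scaled to those probes. With fewer miRNAs tested the number still called was 68 of 68 (mean of at least 50) and 52 of 52 (viral filter; viral mean subtracted), and with only the 2 groups compared, which removes samples, 35 of 57. Signal over background limits low miRNAs: 316 of 467 had a mean below the viral threshold, and a limit set by depth was not tested. Only the 2 groups compared was not run for comparisons of 4 groups.

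miR-7a for the mean of both regions had a log2 fold change of 1.15 in edgeR, 1.15 in DESeq2, 1.18 without the 2 libraries, and 0.74 to 1.17 without 1 library. The 2 libraries include APP/PSEN1 hippocampus replicate 1, with miR-7a at 173, so leaving them out had to raise this fold change. The miRNAs called for the mean of both regions were 1 in edgeR, 1 in DESeq2, 1 without the 2 libraries and 0 to 1 without 1 library. In cortex DESeq2 called 1 miRNA, miR-7a at 1.29. The difference between regions was 0.27 for miR-7a and 0.14 for miR-7b without the 2 libraries, and -0.59 to 0.28 and -0.59 to 0.092 without 1 library. miR-7b in hippocampus was -0.15 to 0.53 without 1 library. miR-7b between WT regions, -0.19 as deposited, was 0.0096 after quantile normalization, 0.15 after median centring, 0.064 in edgeR, 0.094 in DESeq2, 0.018 with the viral covariate and -0.46 to 0.083 without 1 library. None of these miR-7b values passed, and the cause was not tested.

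The 51 miRNAs between WT regions were 28 after median centring, 24 with only the 2 groups compared, 30 with the genotype and replicate block and 25 to 57 without 1 library. The 19 in APP/PSEN1 were 42 with trend and robust settings, 1 with the genotype and replicate block, 45 in DESeq2, 46 with the viral filter, 48 with the viral mean subtracted, 35 with the viral covariate, 12 without the 2 libraries and 0 to 20 without 1 library. The 107 over both genotypes were 58 without the 2 libraries and 63 to 128 without 1 library. The cause was not tested, except that the viral filter tests fewer miRNAs and the other settings that leave out libraries have fewer samples.

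Replicate numbers are shared between groups, and the labels do not say that they pair samples. Of 18 same-number pairs 7 had a correlation over 0.1 (range -0.30 to 0.51), and 4 of 12 samples correlated best with their own number, so the numbers were not used as pairs. Only cortex and hippocampus samples of the same genotype could come from 1 mouse. Those same-number pairs had correlations of -0.13, 0.38 and -0.02 in WT and -0.12, -0.20 and 0.22 in APP/PSEN1. Samples from the same mice are not excluded by this check. The replicate block gave 46, 18 and 108 miRNAs between regions in WT, APP/PSEN1 and both, and the genotype and replicate block gave 30, 1 and 105.

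Lists by camera were 1 in cortex and 2 for the mean of both regions, and 0 and 0 with the estimated correlation, 0 and 0 with fry, 0 and 0 after quantile normalization, 0 and 0 with the viral filter and 0 and 0 without the 2 libraries. Between regions the 0 lists of camera were 2 in WT, 2 in APP/PSEN1 and 3 over both with fry, and in WT 1 without a filter and 1 with the replicate block; fry tests a list on its own and camera against the other miRNAs.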

Other observations

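The tests of this part on depth, scaling, counting error and the lower background of 1 library were chosen only after the results they weigh were seen, as was the region comparison averaged over genotypes, which uses all 12 samples. In that comparison 107 miRNAs differed in limma, 33 higher and 74 lower in hippocampus (179 with an unadjusted p under 0.05; edgeR 118, DESeq2 115). miR-142-5p, an miRNA of blood-derived and microglial cells, rose (log2 fold change 1.14, SE 0.26, adjusted p = 0.00895) from 152 ± 65.1 (SD, n = 3) to 330 ± 156 in WT and from 147 ± 27.8 to 332 ± 82.7 in APP/PSEN1. miR-543, of the imprinted Dlk1-Dio3 cluster, fell from 906 ± 72.8 to 353 ± 188 in WT and from 769 ± 32.4 to 378 ± 225 in APP/PSEN1 (-1.43, SE 0.38, adjusted p = 0.0194). miR-1937a+miR-1937b (2.34, adjusted p = 0.000105), miR-1937c (1.71), miR-720 (1.63), miR-2134 (1.63), miR-2141 (1.59), miR-9 (1.14), miR-222 (1.07), miR-669f (1.07), miR-99a (1.05), miR-92b (1.04) and miR-2132 (1.02) rose. miR-335-5p (-1.57), miR-1 (-1.49), miR-139-3p (-1.39), miR-23a (-1.35), miR-592 (-1.34), miR-135a (-1.32), miR-717 (-1.29), miR-211 (-1.18), miR-2183 (-1.18), miR-132 (-1.17) and miR-743a (-1.07) fell. miR-7a and miR-7b did not pass (-0.67, adjusted p = 0.0879; -0.35, adjusted p = 0.305). Of the 74 lower miRNAs 45 lay below the viral threshold, against 6 of the 33 higher ones. The split was 57 of 112 higher after quantile normalization and 65 of 86 after median centring. The count was 63 without WT hippocampus replicate 2, 64 without APP/PSEN1 hippocampus replicate 1, 66 without APP/PSEN1 cortex replicate 3, 70 without APP/PSEN1 cortex replicate 1 and 71 without WT hippocampus replicate 1.

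By list over both genotypes, no list passed camera (lowest adjusted p 0.131, let-7 and miR-98 family, 3 members rose and 2 fell of 9). fry found 3 lists lower on balance. The oligodendrocyte-enriched list (adjusted p = 8.7e-05) had miR-23a and miR-219 (-0.76, adjusted p = 0.0161) fall of 5, and all 5 members below 0. The activity-regulated list (0.00121) had 3 fall of 5, among them miR-132 and miR-212 (-1.01), which are made from 1 transcript. The erythrocyte list (0.0143) had miR-144 (-0.63, adjusted p = 0.0161) and miR-451 (-0.57, adjusted p = 0.0322), both made in red blood cells, fall of 5. After median centring fry gave 0.377, 0.494 and 0.999 for the 3 lists.

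One APP/PSEN1 hippocampus library, replicate 1, had miR-7a at 173, near the WT hippocampus mean of 227, while the other 5 APP/PSEN1 libraries had 510 to 824. The same library had the lowest miR-7b value of the 12 libraries, 107, against 229 and 269 in replicates 2 and 3 of its group. Counting error at its low depth did not account for the miR-7a value, since the 95% Poisson interval of its 76 miR-7a counts ended at 216 in deposited units. Lower background did not either, since less the viral mean its miR-7a value was 0.318 of the lowest other APP/PSEN1 value. A mislabelled sample could not be told from variation between samples, since 0 other miRNAs passed between the genotypes in hippocampus without it. A biological difference in this 1 sample was not tested, because the design repeats no sample.

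Low-signal miRNAs led the cortex genotype list, with 9 of 10 lower in APP/PSEN1 at a median log2 fold change of -0.77. The viral probes, for miRNAs that uninfected mice do not make, had a median of -0.27 in the same comparison, so a background difference could have added to these values and cannot be excluded. Without WT cortex replicate 1, the library with the highest background, the median was -0.64 with an SD of 0.25 between the 9. These miRNAs were picked with that library included, so its background stays open as well. Of 33 viral probes 0 passed between the genotypes.

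Probes for tRNA fragments, miR-720 and miR-1937, were among the largest increases in hippocampus. Between libraries of overlapping depth (298387 to 326827 counts; 3 hippocampus, 2 cortex), miR-720 and miR-1937a+miR-1937b kept at least 0.771 of their log2 difference, against depth as the cause. miR-1937c kept 0.533. The 2 cortex libraries in that range, WT replicate 1 and APP/PSEN1 replicate 3, also had the highest viral means in cortex (91.3 and 70.8). They had the highest cortex miR-1937c values too (100 and 150), so depth and background cannot be told apart for miR-1937c. Under quantile normalization the 3 probes kept at least 0.901, against scaling as the cause. Median centring could not weigh against scaling, since it shifts all fold changes of a comparison by 1 constant. The region medians were negative, so it had to raise these increases (to 1.98 for miR-720, 2.69 for miR-1937a+miR-1937b and 2.05 for miR-1937c). The biological alternative, a regional difference in tRNA fragments, could not be told apart from a difference in RNA handling between the tissues, because the labels give no dissection order or time.

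Other splits of the samples were tested with the same calls. For the genotype over both regions, 100 of 100 splits gave at least the real 0 miRNAs (highest other 1). Any split must reach 0, so a real count of 0 decides nothing here or below. At least the real 2 lists came from 40 of 100 splits (highest other 7), so chance cannot be excluded for those lists. For the difference between regions, 100 of 100 gave at least the real 0 miRNAs (highest other 104) and at least the real 0 lists (highest other 9), as any split must. The split with 104 calls set 6 libraries with a viral mean of 63.4 against 6 with 42.7, with overlapping ranges (48.3 to 91.3 and 28.5 to 56.0). A split with that many calls points to a possible structure of the samples, but it was picked as the highest of 100, of which 4 had any call, and neither a structure nor a link to background was tested. For regions over both genotypes, only the real split reached 107 miRNAs (1 of 100, highest other 35), so a random split seldom gives that many. The smallest share that 100 splits can show is 1 of 100. Splits of the region labels also cannot tell region from background or depth that differ with it. The split with 35 kept all WT libraries in their regions and exchanged 1 APP/PSEN1 cortex library with 1 APP/PSEN1 hippocampus library, so it holds most of the real difference. All 100 splits gave at least the real 0 lists for regions over both genotypes (highest other 9), as any split must.

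Within a region or genotype only 10 splits exist, too few for a share under 0.05. In cortex, the real genotype split had 0 miRNAs (highest other 0) and 1 list (highest other 7; 9 of 10 splits had at least as many). In hippocampus it had 0 miRNAs (highest other 0) and 0 lists (highest other 6). The region splits had 51 miRNAs in WT (highest other 0) and 19 in APP/PSEN1 (highest other 0), with 0 lists in both (highest other 8 and 4).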
